A study of Rattus norvegicus with 56 samples.

How the data were processed

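Total RNA from the dorsal striatum of 56 male Sprague Dawley rats (Crl:OFA) was labelled from 100 ng with a 3' IVT express kit and hybridized to Affymetrix Rat230_2 arrays, with 1 array per rat. Per the submitters' processing notes the signals were made with MAS5; neither its version nor its scaling target is stated. The deposited values are log2 signals. This was checked on the values: raised to the power of 2, they give a trimmed mean (2% off each end) between 150.042 and 150.046 on every array, so the authors had scaled each array to a common level. The values were used as deposited, with no further normalization, background step or pseudocount. Detection calls were not at hand, so no probe set was called present or absent, and the number of arrays limits the precision.

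The table holds 31099 probe sets, of which 57 are controls. Of the 31042 others, the 18625 with a mean log2 signal above the 40th percentile (4.99) were tested. Among those, 13612 carry 1 gene symbol, 311 carry several and 4702 carry none. The symbols were checked against the rat gene table by gene number: 99.7% matched and 0 symbols were updated. No genome sequence was used, so no positions are given. Where a gene has several probe sets, a named gene's value is that of the probe set the rule below selects, and in the list tests the probe set of highest mean stands for the gene. Myh1 is given from 1 probe set for the lesion and L-dopa and from another for pramipexole and the interaction.

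The labels cross model (lesioned or sham), treatment (L-dopa or saline) and conditioning (pramipexole or saline), with 7 rats in each of the 8 groups. Groups were taken from these labels. Rat numbers are not shared between groups, so samples were not paired. limma 3.58.1 in R 4.3.3 was fitted to the 8 group means of all 56 arrays with no intercept, followed by eBayes. The 14 contrasts were 3 main effects of 28 against 28 rats, 7 comparisons of 7 against 7 and 4 interactions. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Beside a change, the text gives its SE and the number of rats of the named group that lie beyond the mean of their matched comparison group. All limma tests were two-sided.

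The 25 gene lists were fixed from textbook knowledge before the data were examined. The 14 pathway lists are D1 medium spiny neurons, D2 medium spiny neurons, striatal dopamine signalling, immediate early genes, genes linked to L-dopa-induced dyskinesia, neuropeptides and opioid receptors, glutamate receptors and postsynaptic density, GABA signalling, circadian clock, glucocorticoid-responsive genes, unfolded protein and heat shock response, oxidative phosphorylation, interferon response and antigen presentation, and dopamine neuron terminals. The 11 cell type lists are striatal interneurons, microglia, astrocytes, oligodendrocytes, endothelial and mural cells, blood cells, choroid plexus, ependyma, leptomeninges, cerebral cortex, and septum, thalamus and pallidum. They hold 483 members, of which 64 have no probe set with that symbol alone, and some genes stand in several lists. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A score of a list is the mean of its members' signals, each centred on its mean over the 56 arrays. Scores were compared between groups of 7 with two-sided exact permutation tests over 3432 splits, a choice made after the values were seen, and so was the 3' minus 5' signal, adjusted over 7 comparisons.

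Named genes follow a rule written before the data were examined. For each comparison these are up to 10 genes with the largest rise and 10 with the largest fall among called probe sets with 1 symbol. Where fewer than 5 genes pass, they are the 5 of smallest p. From each list they are up to 4 members that pass when adjusted over the list alone, or where none passes up to 2 of smallest p. Drd1, Drd2, Drd3, Penk, Pdyn, Tac1, Fosb and Th were always included; the rest of that part of the rule was not analysed here. Probe sets with several symbols or none were named only where 8 or fewer were called, and this was chosen after their values were seen.

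Arrays numbered 38 to 56 differ from arrays 1 to 37, a position found from the values and not given by the labels. Each comparison was therefore also fitted with the array set as a block, and within a set where a set holds rats of both groups. Other alternatives were no filter, a filter at the 60th percentile, quantile normalization, an intensity trend with a robust prior, array weights, fewer groups in the fit, and covariates for RNA quality (the 3' minus 5' signal of rat control genes), choroid plexus and cerebral cortex. The last ones were leaving out rat 2, leaving out each rat in turn, and adding 16 to the unlogged signal. The pipeline was tested on simulated values, drawn as independent normal noise with the mean and residual SD of each of the 18625 probe sets. Changes were added to 100 probe sets at each size. The simulation held no array step, no correlation between genes and no outlying rats. Its recovery and false calls therefore do not describe the measured arrays in those respects. With 28 against 28 rats, 100 of 100 changes of 0.5 and 100 of 100 of 1 were recovered, with 8 false among 214 calls; the other 6 calls were members of the immediate early list, which had been shifted by 0.2. With 7 against 7, 81 of 100 changes of 0.5 and 98 of 100 of 1 were recovered, with 11 false among 190 calls.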

Results

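Gene expression was measured on arrays in the dorsal striatum, the main target of nigral dopamine neurons, in 56 rats. Lesioned rats had a bilateral loss of nigral neurons induced with an AAV vector, and sham rats had received the same vector expressing GFP. From 5 weeks after surgery the rats were given L-dopa methyl ester (50 mg/kg, with benserazide, which blocks its conversion outside the brain) or saline for 3 weeks. They then went through place conditioning, a test of drug reward, with the D2/D3 dopamine receptor agonist pramipexole (2 mg/kg, 40 min sessions) or saline. Tissue was taken 24 or 48 hours after the last dose. Each of the 8 combinations held 7 rats. The question named by the series is how pramipexole reward after a nigral lesion and L-dopa relates to transcription. Median log2 signals of the arrays lay between 5.62 and 5.81, and correlations between arrays, across probe sets, between 0.960 and 0.987.

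Signals of 15 probe sets separated arrays numbered 1 to 37 from arrays 38 to 56 without overlap, against at most 1 at any other position from 7 to 49. Camk2n1, which encodes an inhibitor of CaM kinase II, averaged 8.02 ± 0.17 (SD, n = 37) in the lower numbers and 7.12 ± 0.15 (n = 19) in the higher. Gosr1, a Golgi transport gene, averaged 8.17 ± 0.54 and 6.40 ± 0.34. Prkcb averaged 7.08 ± 0.17 and 6.30 ± 0.20, and the transcription factor gene Jund 10.13 ± 0.08 and 9.60 ± 0.10. All 28 lesioned rats and the 7 sham rats given both drugs lie in arrays 1 to 37. The sham rats treated with saline all lie in arrays 38 to 56, and the sham rats given L-dopa and saline conditioning are divided into 2 and 5. A step along the array numbers therefore coincides with most of the lesion comparison and with part of the L-dopa comparison. The array set was therefore also fitted as a block, and the calls that this ends are counted or named with each comparison.

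**Figure D1:**
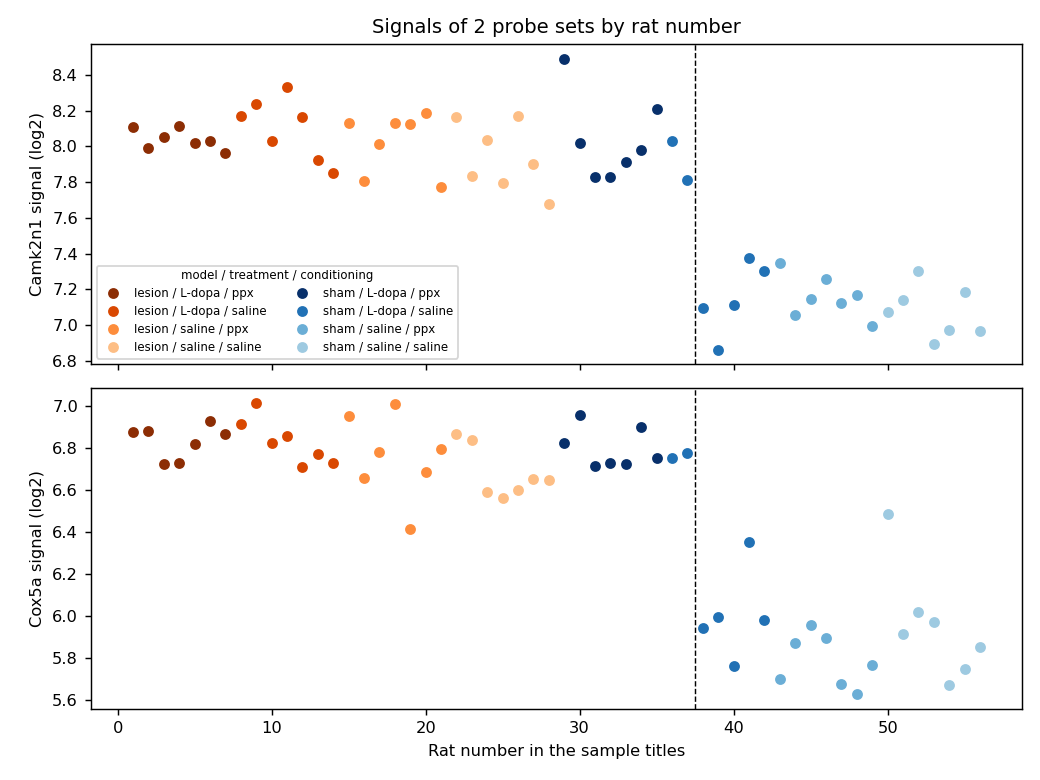
Log2 signal of Camk2n1 and Cox5a in each of the 56 rats against the rat number in the sample titles, coloured by group, with a dashed line between rats 37 and 38. The 5 sham L-dopa rats numbered 38 to 42 lie with the sham rats given saline treatment, and the 9 sham rats numbered 29 to 37 lie with the lesioned rats.

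Lesioned rats were compared with sham rats over all drug groups (28 against 28), the question being what the nigral lesion does to the striatum. Among the genes with the largest rises, Gosr1 was higher by 1.09 ± 0.15 (SE), Tpm3, a tropomyosin gene, by 0.84 ± 0.09 and Myh1 by 0.82 ± 0.08. Camk2n1 was higher by 0.62 ± 0.06 and Cox5a, a subunit of cytochrome c oxidase, by 0.59 ± 0.05. They were higher in 24 to 26 of the 28 lesioned rats, with adjusted p from 2.3e-11 to 3.1e-06. The others, Prkcb, C8h11orf87, Psmd14, Tmem14a and Rab14, rose by 0.47 to 0.57, although another Rab14 probe set was called the other way. Gosr1, Myh1, Camk2n1, Prkcb, Psmd14, Tmem14a and Rab14 have probe sets among the 15 that separated the array sets without overlap. Among the largest falls, Stxbp6 changed by -0.48 ± 0.11 (adjusted p = 0.0047), the chemokine receptor gene Cxcr5 by -0.45 ± 0.09 (adjusted p = 9.7e-04), and Zfp423 by -0.42 ± 0.07 (adjusted p = 1.0e-04). They were lower in 25, 25 and 27 of 28 rats. Adamtsl5, Scd2, Cul4a, Prpf4b, Sdsl, Mast3 and Giot1 fell by 0.36 to 0.41, and another Scd2 probe set was called the other way. The other probe sets of C8h11orf87, Mast3 and Sv2b had the opposite sign without being called. For Myh1 and Camk2n1 the probe set of highest mean is a different one and did not show the rise. Group means of Myh1 on it were 11.71 to 12.04 in lesioned and 11.84 to 12.06 in sham groups. Those of Camk2n1 were 10.82 to 10.97 and 10.82 to 10.96.

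The clock gene Hlf rose by 0.17 ± 0.02 (adjusted p = 3.1e-06, 27 of 28 rats) and Per3 by 0.18 ± 0.05 (adjusted p = 0.041), while Bmal1, which encodes their activator, fell by 0.13 ± 0.04 (adjusted p = 0.0497). The clock list as a whole was not called (11 of 17 members positive, adjusted p = 0.201). Penk, the enkephalin precursor of D2 medium spiny neurons, rose by 0.11 ± 0.04 (adjusted p = 0.049, 22 of 28 rats), and its adjusted p was 0.069 over all probe sets without the filter. Genes of oxidative phosphorylation were higher in 30 of 42 members, with a median of only 0.03 (adjusted p = 5.5e-05). That call did not hold with an estimated correlation (adjusted p = 0.957), and 3 members (Cox5a, Ndufs7 and Uqcrq) passed over all genes and 3 when adjusted over the list alone. Acta2, a smooth muscle marker in the endothelial and mural list, fell by 0.23 ± 0.05 (adjusted p = 0.0012) and Sv2b of the cortical list by 0.23 ± 0.07 (adjusted p = 0.030). Jund, which has a probe set among the 15 that showed the array step, rose by 0.37 ± 0.03 (adjusted p = 3.2e-11). Markers of dopamine terminals did not pass: Sncg differed by -0.44 ± 0.23 (adjusted p = 0.285) and Aldh1a1 by -0.14 ± 0.07 (adjusted p = 0.245). Of the list's 4 tested members 0 were positive (adjusted p = 0.527). Among the other striatal genes followed throughout, Pdyn differed by -0.16 ± 0.07, Tac1 by -0.15 ± 0.08, Drd1 by 0.01, Drd2 by 0.06 and Fosb by -0.08, none of them called.

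In all, limma called 414 probe sets higher and 530 lower in lesioned rats, with a median size of 0.17. Of these, 12 exceeded 0.5 and 1 exceeded 1. With the array set as a block 0 were called (803 at unadjusted p under 0.05, where chance gives 931). The changes of Gosr1 and Cox5a were then -0.27 ± 0.30 and 0.07 ± 0.10, and those of Hlf and Penk 0.17 ± 0.06 and 0.15 ± 0.08. Within arrays 1 to 37, where 14 lesioned rats could be set against 9 sham rats, limma called 0 (1035 at unadjusted p under 0.05). Among the 7 lesioned and 7 sham rats given both drugs it called 0 (989 at unadjusted p under 0.05). In those 14 rats Camk2n1 differed by 0.00 ± 0.09, Cox5a by 0.03 ± 0.06 and Acta2 by 0.10 ± 0.08. Hlf differed by 0.19 ± 0.06, Stxbp6 by -0.59 ± 0.22 and Cxcr5 by -0.66 ± 0.18. The smallest adjusted p of limma in these rats was 0.214. All of these genes were picked from calls in a fit that included the same 14 rats, a choice that favours the lesion. A shared direction is therefore partly built in, and these values are no independent check of a lesion effect.

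**Figure D2:**
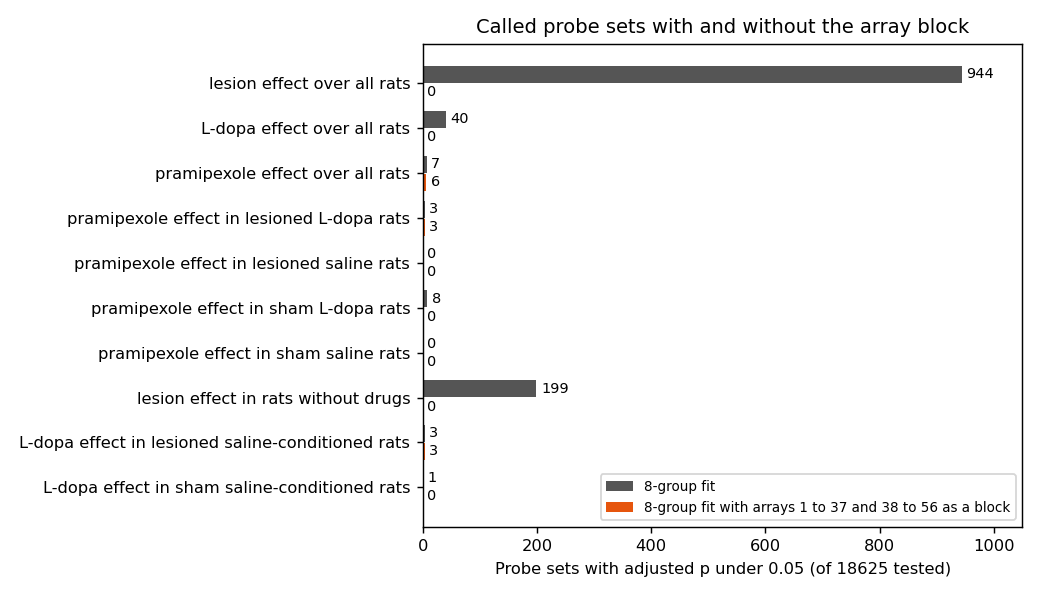
Number of probe sets with adjusted p under 0.05, of 18625 tested, in each of 10 comparisons, with grey bars for the fit of 8 groups and orange bars for the same fit with arrays 1 to 37 and 38 to 56 as a block. The lesion calls go from 944 to 0 and the L-dopa calls from 40 to 0, and the pramipexole calls from 7 to 6.

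The lesion without either drug was compared in the rats given saline treatment and saline conditioning (7 against 7). Gosr1 was higher by 1.60 ± 0.31, Tpm3 by 1.26 ± 0.19, Myh1 by 1.19 ± 0.16, Plekhb2 by 0.97 ± 0.18 and Camk2n1 by 0.86 ± 0.11, in 7 of 7 rats each. Psmd14, Prkcb, Thoc7, Mphosph8 and Cox5a rose by 0.73 to 0.77. Gosr1, Myh1, Camk2n1, Psmd14, Prkcb and Mphosph8 have probe sets among the 15 that showed the array step. Of the falls, Mfhas1 changed by -0.99 ± 0.27 (adjusted p = 0.0498), Trim26 by -0.74 ± 0.17 (6 of 7 rats), Zfp423 by -0.66 ± 0.14 and Calr, an endoplasmic reticulum chaperone gene, by -0.57 ± 0.14 (adjusted p = 0.028). Gusb, Misp3, Tlk1, Wnt1, Rab1b and Mapkapk2 fell by 0.50 to 0.59, and Acta2 fell by 0.43 ± 0.09. The other probe sets of Camk2n1, Tlk1 and Rab1b had the opposite sign without being called. The Myh1 probe set of highest mean, a different one, averaged 11.71 in lesioned and 11.88 in sham rats. Genes linked to L-dopa-induced dyskinesia were higher in 13 of 15 members (median 0.12, adjusted p = 0.016, and adjusted p = 0.784 with an estimated correlation; 0.082 with the array block). Of these, 0 passed over all genes and 1 adjusted over the list alone, Rasgrp1 (0.41 ± 0.12), which encodes a Ras activator. Oxidative phosphorylation genes were higher in 27 of 42 (median 0.02, adjusted p = 0.034, and adjusted p = 0.878 with an estimated correlation). limma called 125 probe sets higher and 74 lower. With the array block it called 0 (818 at unadjusted p under 0.05), Gosr1 differed by -0.41 ± 0.47 and Cox5a by -0.03 ± 0.16. No array set holds both groups, so no within-set value could be had. The 3' minus 5' signal of control genes, a measure of RNA quality, averaged 0.87 ± 0.10 (SD, n = 7) in lesioned and 1.06 ± 0.15 in sham rats (exact permutation p = 0.017, adjusted p = 0.061 over 7 such tests). With it as a covariate limma called 125 probe sets, of which 74 were among those called without it. Neither list was then called (median 0.065 and adjusted p = 0.254 for dyskinesia-linked genes, median -0.019 and adjusted p = 0.766 for oxidative phosphorylation). Leaving out rat 28 or rat 54 also ended the first call (adjusted p = 0.110 and 0.104), and any 1 of 6 rats the second (up to 0.372, without rat 24).

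L-dopa was compared with saline treatment over all rats (28 against 28), the question being what 3 weeks of the drug leave behind. Gosr1 was higher by 0.75 ± 0.15 (adjusted p = 0.011), Cox5a by 0.38 ± 0.05 (adjusted p = 8.6e-05, 24 of 28 rats) and the phosphate transporter gene Slc20a2 by 0.36 ± 0.08 (adjusted p = 0.047, 24 of 28). Myh1, Camk2n1, Slc25a44, Pgm3, C8h11orf87, Prkcb and Tmem14a rose by 0.25 to 0.34, and Jund by 0.20 ± 0.03. Gosr1, Myh1, Camk2n1, Prkcb, Tmem14a and Jund have probe sets among the 15 that showed the array step. Zc3h10 changed by -0.18 ± 0.04, Slc35a1 by -0.16 ± 0.04, Ahctf1 by -0.13 ± 0.03 and Sdhaf3, an assembly factor of respiratory complex II, by -0.13 ± 0.03. Markers of D1 medium spiny neurons were lower in 8 of 9 members (median -0.09) and markers of cerebral cortex higher in 11 of 13 (median 0.20), each with adjusted p = 0.0086, and adjusted p = 0.788 with an estimated correlation. Glutamate receptor and postsynaptic genes were higher in 20 of 30 (adjusted p = 0.0086, and adjusted p = 0.788 with an estimated correlation), with Grm3 (0.14 ± 0.04) and Shank2 (0.14 ± 0.04) passing when adjusted over the list alone and 0 over all genes. Microglial markers were higher in 14 of 14 (median 0.12, adjusted p = 0.0073, and adjusted p = 0.788 with an estimated correlation), which rested on rat 2 (adjusted p = 0.322 without it). Oxidative phosphorylation genes were lower in 35 of 42 (adjusted p = 0.0073) against the rise of Cox5a, and genes of the unfolded protein and heat shock response in 21 of 24 (adjusted p = 0.0086). Both had adjusted p = 0.788 with an estimated correlation.

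limma called 35 probe sets higher and 5 lower with L-dopa. With the array block it called 0 (1012 at unadjusted p under 0.05). Gosr1 then differed by 0.11 ± 0.18, Myh1 by -0.0057 ± 0.09 and Slc20a2 by 0.37 ± 0.12. The list tests then gave adjusted p = 0.058 for D1 neurons and for the unfolded protein response, 0.219 for cortex and for oxidative phosphorylation, 0.261 for glutamate genes and 0.099 for microglia. Within arrays 1 to 37 (14 against 14) 3 were called, 2 higher and 1 lower. Within arrays 38 to 56 (5 against 7) 0 were called by limma (1079 at unadjusted p under 0.05). The 3' minus 5' signal averaged 1.07 ± 0.10 (SD, n = 28) with L-dopa and 0.97 ± 0.12 without. With it as a covariate limma called 18 probe sets, of which 12 were among those called without it, and 1233 in place of 2022 had unadjusted p under 0.05. None of the 6 lists was then called (adjusted p from 0.325 to 0.599). The median went from 0.20 to 0.14 for cortex (adjusted p = 0.570) and from -0.09 to -0.048 for D1 neurons (adjusted p = 0.482).

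In lesioned rats without pramipexole, L-dopa (7 against 7) lowered Peli2, which encodes a ubiquitin ligase of innate immune signalling, by 0.46 ± 0.09 (adjusted p = 0.033, 7 of 7 rats). Probe sets without a symbol, 2 in number, rose by 0.34 ± 0.07 and 0.80 ± 0.15. Cortical markers were higher in 12 of 13 members (median 0.45, adjusted p = 6.0e-04, and adjusted p = 0.473 with an estimated correlation), among them Neurod2 at 0.91 ± 0.24, the 1 that passed when adjusted over the list alone, with 0 over all genes. D2 medium spiny neuron markers were lower in 5 of 5 (median -0.22, adjusted p = 0.016) and D1 markers in 7 of 9 (median -0.21, adjusted p = 0.021; Tac1, the substance P precursor, at -0.47 ± 0.16). Both had adjusted p = 0.473 with an estimated correlation. Lower too were striatal dopamine signalling genes in 20 of 23 (adjusted p = 0.0095, and adjusted p = 0.552 with an estimated correlation). Glutamate receptor genes were higher in 19 of 30 (adjusted p = 0.038; Shank2 0.35 ± 0.08, Shank1 0.56 ± 0.18) and immediate early genes in 16 of 20 (adjusted p = 0.038). With an estimated correlation these had adjusted p = 0.473 and 0.576. Oxidative phosphorylation genes were lower in 31 of 42 (adjusted p = 6.0e-04) and unfolded protein response genes in 20 of 24 (adjusted p = 0.021). Both had adjusted p = 0.552 with an estimated correlation. The 3' minus 5' signal averaged 1.11 ± 0.09 (SD, n = 7) with L-dopa and 0.87 ± 0.10 without (exact permutation p = 0.0012, adjusted p = 0.0082 over 7 such tests), so RNA quality differs along with the drug here. With it as a covariate limma called 1 probe set, 1115 in place of 2397 had unadjusted p under 0.05, and Peli2 was at -0.56 (adjusted p = 0.015). None of the 8 lists was then called (adjusted p from 0.234 to 0.780). The median went from 0.45 to 0.29 for cortex (adjusted p = 0.234), from -0.22 to -0.065 for D2 neurons (adjusted p = 0.326) and from -0.21 to -0.018 for D1 neurons (adjusted p = 0.707). Leaving out single rats ended 6 of the 8 calls, all but cortex and oxidative phosphorylation, with 3 to 8 such rats per list. The highest adjusted p came without rat 9 for dopamine signalling, D1 (0.099) and D2 (0.073), without rat 13 for immediate early (0.312), rat 25 for glutamate (0.111) and rat 23 for unfolded protein response genes (0.105). The values of the cholinergic genes Chat (-0.46 ± 0.16) and Slc5a7 (-0.39 ± 0.14) passed only when adjusted over their own list. So did those of Abat (-0.43 ± 0.11), of Ret (-0.70 ± 0.22), of Crabp2 (-0.38 ± 0.12) and of the choroid plexus marker Ttr (-2.26 ± 0.68). The cortical marker score averaged 0.19 ± 0.31 (SD) with L-dopa and -0.22 ± 0.56 without, a difference of 0.41. It did not pass an exact permutation test (p = 0.122, adjusted p = 0.754 over 28 such tests). Fitting these 14 rats alone, limma called 0 (2302 at unadjusted p under 0.05).

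In sham rats without pramipexole, L-dopa (7 against 7) lowered Cfdp1, a chromatin gene, by 0.27 ± 0.05 (adjusted p = 0.038, 7 of 7 rats; -0.24 ± 0.05 and adjusted p = 0.206 with the array block). Immediate early genes, which neurons switch on after activity, were higher in 16 of 20 members (median 0.26, adjusted p = 3.9e-05, and adjusted p = 0.650 with an estimated correlation). Dyskinesia-linked genes were higher in 13 of 15 (adjusted p = 0.010) and glutamate receptor genes in 26 of 30 (adjusted p = 0.024). Both had adjusted p = 0.650 with an estimated correlation, and glutamate receptor genes had 0.128 with the array block. Oxidative phosphorylation genes were lower in 37 of 42 (adjusted p = 3.5e-04, and adjusted p = 0.728 with an estimated correlation) and unfolded protein response genes in 19 of 24 (adjusted p = 0.034, and adjusted p = 0.827; 0.062 with the array block). With the 3' to 5' covariate the unfolded protein response call was lost as well (adjusted p = 0.058), while the other lists kept theirs (adjusted p from 8.9e-05 to 0.037). Without rat 54 adjusted p was 0.147 for dyskinesia-linked genes and 0.279 for glutamate receptor and unfolded protein response genes, and the last 2 calls were ended by any 1 of 4 and of 7 rats. In each of these lists 0 members passed over all genes and 0 when adjusted over the list alone. Ddc, the enzyme that converts L-dopa to dopamine, had a value of 0.33 ± 0.11 (adjusted p = 0.383; 0.016 adjusted over the list alone). Within arrays 38 to 56 (5 against 7) limma called 0 (1079 at unadjusted p under 0.05).

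**Figure D3:**
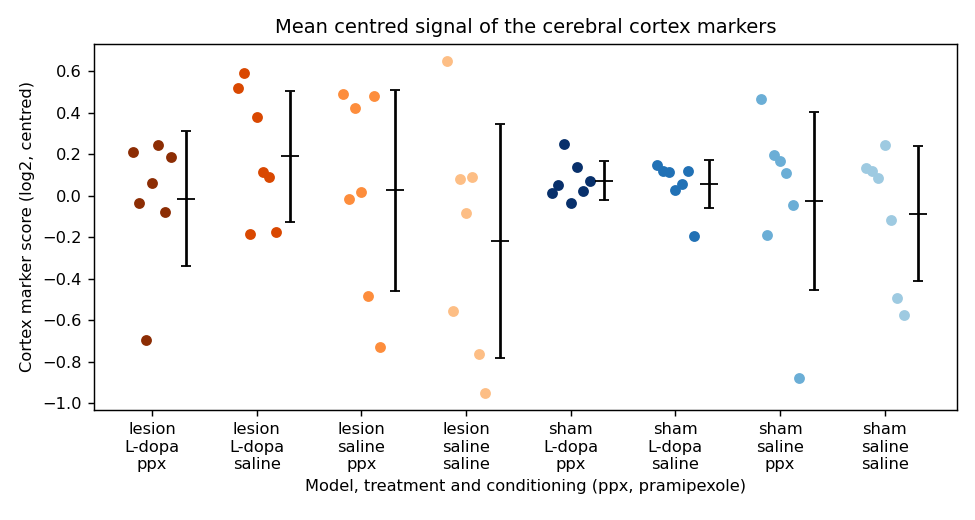
Mean centred log2 signal of the cerebral cortex markers in each rat of the 8 groups, with the group mean and SD (n = 7) beside the points. The lesioned rats without drugs spread from -0.95 to 0.65, and rat 3 of the lesioned rats given both drugs lies at -0.70.

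Pramipexole conditioning was compared with saline conditioning over all rats (28 against 28), the question closest to the series title. Haemoglobin transcripts fell. Hbb, beta globin, fell by 0.51 ± 0.08, or to 0.703 of its level (adjusted p = 0.0013, 26 of 28 rats), with a mean of 10.13 against 10.64. Cd93, a surface receptor gene of endothelial and myeloid cells, changed by -0.39 ± 0.08 (adjusted p = 0.028, 26 of 28). Its signal was dim, with group means of 4.81 to 5.56 where the filter lay at 4.99. The other 5 called probe sets, named after their values were seen, are shared by alpha globin or by beta globin genes and changed by -0.44 to -0.63. Globin genes are near copies of each other, so the gene behind each signal is uncertain. Oligodendrocyte markers were lower in 15 of 16 members (median -0.08, adjusted p = 1.7e-06, and adjusted p = 0.398 with an estimated correlation). Immediate early genes were higher in 16 of 20 (median 0.07, adjusted p = 2.2e-04) and unfolded protein response genes lower in 19 of 24 (median -0.02, adjusted p = 0.0063). Both calls were lost with an estimated correlation (adjusted p = 0.473 and 0.501), and 0 members of the 3 lists passed over all genes. Adjusted over the list alone 2 unfolded protein response genes passed, Hyou1 (-0.30 ± 0.07) and the small heat shock gene Hspb1 (-0.29 ± 0.10). The values of Npy (0.12 ± 0.04), of the postsynaptic scaffold gene Shank3 (0.26 ± 0.08) and of Bmal1 (-0.13 ± 0.04) passed only when adjusted over their own lists. Lss (-0.20 ± 0.05, adjusted p = 0.092) and Commd6 (0.15 ± 0.04, adjusted p = 0.325) were not called. The blood cell list has Hbb as its only tested member (adjusted p = 1.7e-06, and adjusted p = 7.8e-05 with an estimated correlation).

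With the array block limma called 6 probe sets, all among the 7. Hbb differed by -0.54 ± 0.10 (adjusted p = 0.0083) and Cd93 by -0.41 ± 0.09 (adjusted p = 0.128). Within arrays 1 to 37 (21 against 16) limma called 0 (939 at unadjusted p under 0.05), with Hbb at -0.59 ± 0.12 (adjusted p = 0.137). Within arrays 38 to 56 (7 against 7) it called 0 (1073 at unadjusted p under 0.05), with Hbb at -0.36 ± 0.13 (adjusted p = 0.831).

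**Figure D4:**
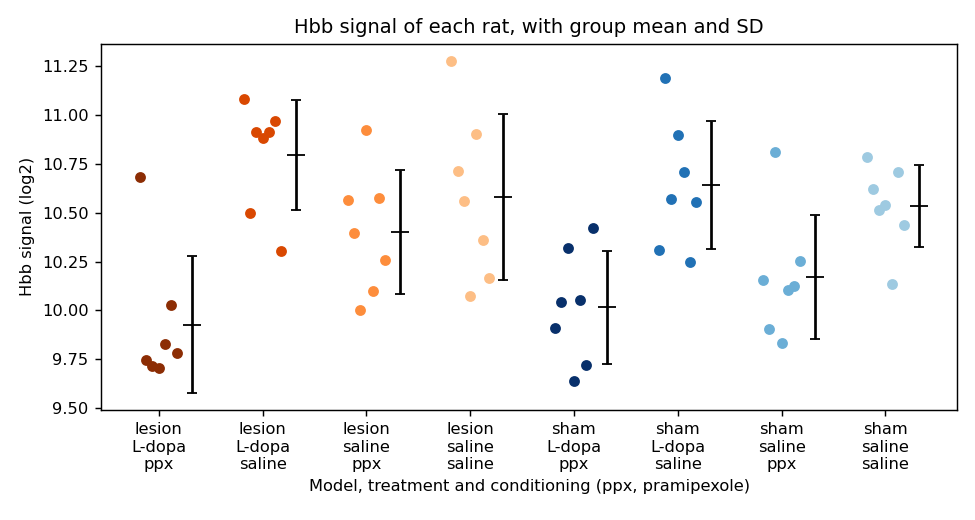
Log2 signal of the Hbb probe set in each rat of the 8 groups, with the group mean and SD (n = 7) beside the points. Within each pair of groups that differ only in conditioning, the pramipexole group has the lower mean, from 9.93 against 10.79 in lesioned L-dopa rats to 10.40 against 10.58 in lesioned rats given saline.

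In lesioned rats given L-dopa, the combination named in the series title, pramipexole (7 against 7) lowered Hbb by 0.87 ± 0.17 (adjusted p = 0.035, 7 of 7 rats). The other 2 called probe sets, shared by globin genes, changed by -0.75 ± 0.15 and -1.04 ± 0.20. Hbb was -0.84 with adjusted p = 0.133 when rat 2 was left out, and limma then called 0 probe sets (899 at unadjusted p under 0.05). Fitting these 14 rats alone it called 0 as well (1019 at unadjusted p under 0.05). Microglial markers were higher in 14 of 14 members (median 0.41, adjusted p = 1.0e-05, and adjusted p = 0.525 with an estimated correlation). Interferon and antigen presentation genes were higher in 17 of 19 (median 0.35, adjusted p = 7.4e-04, and adjusted p = 0.633). Both rested on rat 2, whose microglial score was 2.57 against -0.22 to 0.13 in the other 6 rats. Without it adjusted p was 0.823 and 0.666, and the interferon median turned to -0.01. D2 neuron markers were higher in 5 of 5 (median 0.16, adjusted p = 0.021, and adjusted p = 0.525 with an estimated correlation). Cortical markers were lower in 12 of 13 (median -0.21, adjusted p = 0.019, and adjusted p = 0.657) and choroid plexus markers higher in 4 of 5 (adjusted p = 0.027, and adjusted p = 0.525). Without rat 3 the D2 and cortical calls were lost (adjusted p = 0.182 and 0.199), with medians of 0.10 and -0.09. Without rat 7, whose choroid plexus score was 2.24 against -0.48 to 0.22 in the other 6, the choroid plexus median went from 0.23 to 0.01 (adjusted p = 0.552). Leaving out rat 8, 9, 11 or 12 also ended 1 or more of these 3 calls (adjusted p from 0.054 to 0.118). The values of Ttr (2.49 ± 0.68) and Crabp2 (0.47 ± 0.12) passed only when adjusted over their own lists. Sppl2a (0.57 ± 0.13), Tmem64 (0.31 ± 0.07), Trim9 (-0.33 ± 0.08) and Tmem223 (0.31 ± 0.08) were not called.

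In lesioned rats given saline, pramipexole (7 against 7) left 0 probe sets called by limma (1331 at unadjusted p under 0.05). The gene nearest to the threshold was Mfhas1 (1.38 ± 0.27, adjusted p = 0.075, 7 of 7 rats; 0.047 without rat 2), followed by Nasp (-0.49 ± 0.10), Mapk11 (0.47 ± 0.11), Tle2 (0.38 ± 0.09) and Gga3 (0.30 ± 0.07). Cortical markers were higher in 13 of 13 members (median 0.25) and immediate early genes in 18 of 20 (median 0.18), each with adjusted p = 0.019, and adjusted p = 0.758 with an estimated correlation. Unfolded protein response genes were lower in 19 of 24 (median -0.05, adjusted p = 0.019; Hyou1 -0.50 ± 0.15) and oligodendrocyte markers in 13 of 16 (median -0.12, adjusted p = 0.0049). Both had adjusted p = 0.758 with an estimated correlation. Each of the 4 calls was ended by leaving out any 1 of 2 to 6 rats, rat 20 among them (adjusted p = 0.258 for cortical and oligodendrocyte markers, 0.431 for immediate early and 0.209 for unfolded protein response genes).

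In sham rats given L-dopa, pramipexole (7 against 7) went with higher Myh1 (0.76 ± 0.12), Camk2n1 (0.67 ± 0.11), Cox5a (0.58 ± 0.11), Wdtc1 (0.44 ± 0.09), Atxn2 (0.42 ± 0.07) and Jund (0.34 ± 0.07) and with lower Rlim (-0.39 ± 0.08), in 7 of 7 rats each, with adjusted p from 0.0011 to 0.028. A probe set without a symbol rose by 0.58 ± 0.10. It is among the 15 that showed the array step, and Myh1, Camk2n1, Atxn2 and Jund also have probe sets among those 15. For Myh1, Camk2n1 and Atxn2 the probe set of highest mean is a different one and did not show changes of this size. On it Myh1 averaged 12.04 with pramipexole and 12.06 without, Camk2n1 10.96 and 10.92, and Atxn2 9.83 and 9.73. Oxidative phosphorylation genes were higher in 37 of 42 (median 0.04, adjusted p = 9.8e-06, and adjusted p = 0.663 with an estimated correlation). Endothelial and mural markers were lower in 12 of 15 (median -0.10, adjusted p = 0.024, and adjusted p = 0.675; 0.169 with the array block), a call ended by leaving out any 1 of 7 rats (up to 0.180, without rat 40). The pramipexole rats are all in arrays 1 to 37 and 5 of the 7 others in arrays 38 to 56. Fitted with the array block, limma called 0 (640 at unadjusted p under 0.05), Myh1 differed by 0.07 ± 0.14, Camk2n1 by 0.12 ± 0.13 and Jund by -0.05 ± 0.08. Within arrays 1 to 37 (7 against 2) it called 0 (700 at unadjusted p under 0.05). Hbb had a value of -0.62 ± 0.17 (adjusted p = 0.262).

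In sham rats given saline, immediate early genes were higher with pramipexole (7 against 7) in 17 of 20 members (median 0.25, adjusted p = 3.7e-10). That call was lost with an estimated correlation (adjusted p = 0.183). Of the members, 0 passed over all genes and 7 adjusted over the list alone, among them Nr4a1 (0.81 ± 0.20, 7 of 7 rats), Arc (0.76 ± 0.26, 6 of 7), Fosb (0.55 ± 0.15, 7 of 7) and Klf10 (0.38 ± 0.11, 7 of 7). The score of the list differed by 0.34, above the saline mean in 6 of 7 rats (exact permutation p = 0.0507, adjusted p = 0.754 over 28 such tests, of which none passed). Dyskinesia-linked genes, which share Nr4a1, Fosb and Arc with that list, were higher in 12 of 15 (adjusted p = 5.1e-04, and adjusted p = 0.335 with an estimated correlation), with 3 passing adjusted over the list alone. Neuropeptide genes were higher in 15 of 20 (adjusted p = 0.024, and adjusted p = 0.529 with an estimated correlation). Oligodendrocyte markers were lower in 14 of 16 (adjusted p = 0.0075), and oxidative phosphorylation genes in 31 of 42 (adjusted p = 0.0042), both with adjusted p = 0.695 with an estimated correlation. Astrocyte markers were lower in 10 of 12 (adjusted p = 0.024; Aldh1l1 -0.29 ± 0.09) and unfolded protein response genes in 16 of 24 (adjusted p = 0.040). These had adjusted p = 0.695 with an estimated correlation too. Of the 7 lists, 5 lost their call without single rats: oxidative phosphorylation without rat 45 (adjusted p = 0.126), and the others without any 1 of 4 to 6 rats. Their highest adjusted p was 0.149 for astrocytes, neuropeptides and oligodendrocytes (without rat 51) and 0.273 for the unfolded protein response (without rat 54). limma called 0 single probe sets (1188 at unadjusted p under 0.05). Pbrm1 (0.38 ± 0.09), Pak2 (0.41 ± 0.10), Ift25 (0.40 ± 0.10) and Sh3bgrl1 (0.38 ± 0.09) came nearest, with adjusted p = 0.377. Hbb had a value of -0.36 ± 0.17 (adjusted p = 0.767).

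**Figure D5:**
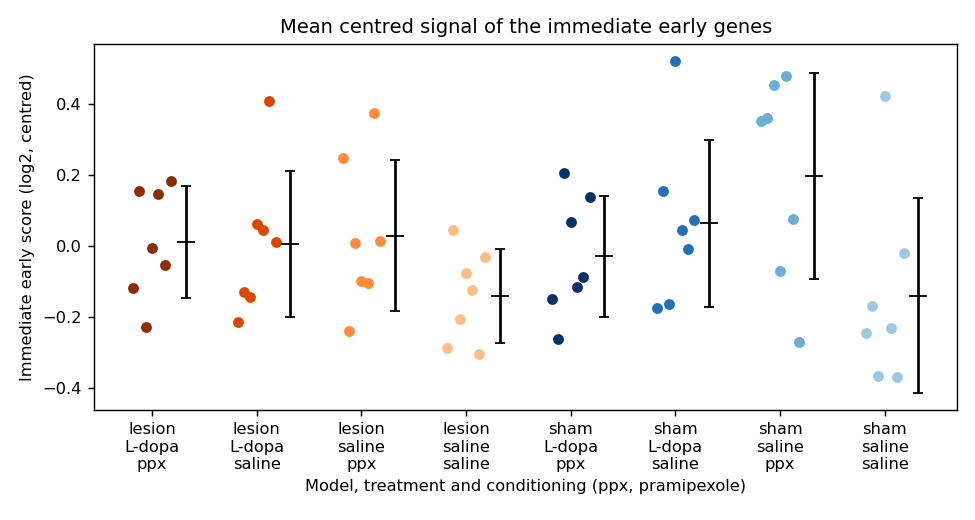
Mean centred log2 signal of the immediate early genes in each rat of the 8 groups, with the group mean and SD (n = 7) beside the points. In sham rats given saline treatment the mean is 0.20 with pramipexole and -0.14 without, and the groups overlap.

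The interactions ask whether an effect differs between backgrounds. The L-dopa effect was smaller in lesioned than in sham rats for Myh1 (-0.67 ± 0.12, adjusted p = 0.035) and for Mphosph8 (-0.40 ± 0.08, adjusted p = 0.047), and these were the only 2 calls of limma over the 4 interactions. Under the array block they were -0.05 ± 0.13 and -0.12 ± 0.10, with 0 calls (681 at unadjusted p under 0.05). Cox5a (-0.53 ± 0.11), Pitpnm1 (0.36 ± 0.07) and Scaper (-0.28 ± 0.06) were not called. Gabrg1 (-0.46 ± 0.12), Jund (-0.27 ± 0.07) and Stat2 (0.48 ± 0.13) passed only when adjusted over their own lists. The pramipexole effect on immediate early genes was lower in L-dopa rats than in saline-treated rats in 17 of 20 members (median -0.30, adjusted p = 1.7e-06, and adjusted p = 0.373 with an estimated correlation). Adjusted over the list alone 3 passed, Fosb (-0.56 ± 0.15), Nr4a1 (-0.61 ± 0.20) and Klf10 (-0.30 ± 0.11), and 0 over all genes. For Hbb the same interaction was -0.47 ± 0.17 (adjusted p = 0.484; unadjusted p = 0.0063, as no other member of its list was tested), so the pramipexole effect was not shown to differ between treatments. limma called 0 probe sets for lesion by pramipexole (1201 at unadjusted p under 0.05), L-dopa by pramipexole (1509) and the three-way term (1090). The values of smallest p were those of Kiaa1549 (0.47 ± 0.10), Cdc25a (0.45 ± 0.10) and Mfhas1 (1.18 ± 0.27) for lesion by pramipexole. For L-dopa by pramipexole they were those of Rnd3 (-0.42 ± 0.09), Zc3h18 (-0.66 ± 0.14) and Usp34 (-0.51 ± 0.12), and for the three-way term those of Atxn2 (-0.68 ± 0.14), Wdtc1 (-0.78 ± 0.18) and Yipf3 (-1.46 ± 0.34).

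The striatal receptor and peptide genes followed throughout were bright. Penk averaged 12.20 ± 0.14 (SD, n = 56), Drd1 10.79 ± 0.20, Tac1 10.36 ± 0.32, Pdyn 9.96 ± 0.27 and Drd2 9.66 ± 0.24. Apart from Penk in the lesion comparison, none of them was called in any comparison. Drd3, the preferred receptor of pramipexole, averaged 3.63 and Th 4.11, below the filter, so neither was among the probe sets tested above. In the limma fit without the filter, Th differed by -0.25 ± 0.11 for the lesion over all rats (adjusted p = 0.223). For the lesion without drugs it differed the other way, by 0.18 ± 0.22 (adjusted p = 0.808). Drd3 differed there by -0.10 ± 0.11 for pramipexole over all rats (adjusted p = 0.997). Of the 25 lists, 8 were not called in any of the 14 comparisons. Their smallest adjusted p were 0.061 for leptomeninges and 0.096 for GABA signalling (both in lesion by L-dopa), 0.063 for striatal interneurons (pramipexole in lesioned L-dopa rats). They were 0.074 for the circadian clock and 0.076 for ependyma (both pramipexole over all rats). They were 0.180 for glucocorticoid-responsive genes (L-dopa in sham rats), 0.197 for dopamine neuron terminals (L-dopa in lesioned rats) and 0.281 for septum, thalamus and pallidum (lesion by pramipexole).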

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

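The tests of the sham rats by array number, of an equal lesion effect, of the haemoglobin change with an array block, of blood vessels, of the share of cortical tissue and of RNA quality were chosen after the results were seen; those of the spike-in controls, of Alas2, of the cortical genes with an array block and of other splits of the rats were written down before.

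The 944 calls between lesioned and sham rats coincide with the step between arrays 37 and 38, as all 28 lesioned rats lie in the first set and all 19 arrays of the second are from sham rats. On 17 probe sets that separate lesioned from sham rats under saline treatment, 9 of the 9 sham L-dopa rats numbered 29 to 37 lay on the lesioned side and 5 of the 5 numbered 38 to 42 on the other; 15 of the 17 are the probe sets that showed the step, so this restates it and adds no support for an array batch, while the lesion by itself does not account for a division of sham rats of 1 group on them. The spike-in controls argue against a batch that acts on labelling or hybridization as a whole (0 of 45 probe sets differed in limma, with 0 at unadjusted p under 0.05). Their largest change between the array sets was 0.099. A batch that acts on particular probe sets need not appear in these controls, so they do not exclude it. Among the 7 lesioned and 7 sham rats given both drugs, the 1220 probe sets called in the other 42 rats moved in the called direction by 0.204 of their change there (95% bootstrap interval 0.018 to 0.371), a ratio that leans low because the 42 rats also chose the probe sets; with probe sets chosen in 4 rats of each group and sizes taken from the 3 others it was 0.269 (0.070 to 0.610), and with those called in all 56 rats, a choice that favours the lesion, 0.58 (0.38 to 0.77). The middle ratio lies below 1 but not under the bounds set for excluding an equal lesion effect under both drugs (0.25, and 0.5 for the interval), so this, a smaller lesion effect, a lesion effect that the drugs change, array lots and tissue handling stay open, and the loss of all calls with the block owes something to larger errors (the median change of the 944 went from 0.17 to 0.11 and the median SE from 0.043 to 0.102).

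Hbb and other globin signals fell with pramipexole. With the block the change was 1.05 of that without it and still past the threshold. Most pairs of groups that differ only in conditioning lie in a single array set, so the block could hardly move it and this ratio decides little. The array step is argued against by the falls inside each set, where it cannot act. Hbb differed there by -0.59 ± 0.12 (arrays 1 to 37) and -0.36 ± 0.13 (arrays 38 to 56), though limma called neither (adjusted p = 0.137 and 0.831). Fewer blood vessels could not be decided: the median change of the 15 endothelial and mural genes was -0.04, or 0.0855 of the Hbb change, with an SD over genes of 0.085 and 10 of 15 lower. Less blood left in the tissue is a candidate explanation, as Alas2, an erythroid gene outside the globin family, followed Hbb over the 56 rats within groups (r = 0.551, permutation p = 4e-05; rho = 0.579, p = 1e-05, the smallest that 100000 permutations can give; r = 0.541 without the 2 farthest rats), though its signal was dim (mean 4.30; change with pramipexole -0.37 ± 0.12). An action of pramipexole on blood or circulation and a difference in the time or way of tissue collection were not tested and stay open.

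Over all rats L-dopa went with higher cortical and lower D1 neuron markers (each with adjusted p = 0.0086, and adjusted p = 0.788 with an estimated correlation), while the D2 list was not called (5 of 5 lower, adjusted p = 0.188); the difference of medians between 6 cortical and 14 D1 and D2 genes was 0.33 (95% bootstrap interval 0.0036 to 0.608). An uneven share of cortical tissue in the dissected pieces may account for part of it: with a score of the other 7 cortical markers as a covariate the difference was 0.15, a ratio of 0.464, but the interval of the ratio (0.037 to 2.61) leaves this undecided. With the array block it was 0.27, a ratio of 0.812 (-0.464 to 1.07), which does not decide either. The 3' minus 5' signal was higher with L-dopa as well (1.07 ± 0.10 against 0.97 ± 0.12, SD, n = 28 each), and with it as a covariate the difference was 0.18, a ratio of 0.542 (-2.80 to 0.918), which leaves RNA quality undecided too. An effect of L-dopa on these neurons stays open.

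Single rats stood far from the other 6 of their group in 21 of 168 groups tested over 21 measures, where chance gives about 1 in 20. Among lesioned rats given both drugs, rat 3 had a cortical score of -0.70 (others -0.08 to 0.24), a D2 neuron score of 0.41 and a Drd2 signal of 10.22. Rat 7 of that group had a choroid plexus score of 2.24 (others -0.48 to 0.22), and rat 1 an Hbb signal of 10.68. Rat 2 of that group had a microglial score of 2.57 (others -0.22 to 0.13) and an interferon score of 2.08 (others -0.40 to 0.30). Rat 12 (lesion, L-dopa, saline) had an oligodendrocyte score of -0.14. Rat 21 (lesion, saline, pramipexole) had a Pdyn signal of 10.48, and rat 22 (lesion, no drugs) a Drd1 signal of 10.25. Rat 29 (sham, both drugs) had an interferon score of 0.29, a D1 neuron score of -0.28, a Drd1 signal of 10.47 and a Tac1 signal of 9.74. Among sham rats given L-dopa and saline, rat 37 had a Drd2 signal of 9.36, rat 40 a Cd93 signal of 5.06, rat 41 an oligodendrocyte score of -0.083 and rat 42 a cortical score of -0.19. Rat 45 (sham, saline, pramipexole) had a 3' minus 5' value of 1.11 (others 0.955 to 1.01) and an Hbb signal of 10.81, and rat 54 (sham, no drugs) a microglial score of 0.49.

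Interaction tests were called for the following. The L-dopa effect differed between lesioned and sham rats for Myh1 (-0.67) and Mphosph8 (-0.40), but both are among the 15 probe sets that showed the array step, and both calls were lost with the array block (-0.05 and -0.12, adjusted p = 1.00 each). The same term was called for oxidative phosphorylation genes (median -0.02, adjusted p = 0.0030, and adjusted p = 0.831 with an estimated correlation; 0.083 without rat 24). The pramipexole effect differed between L-dopa and saline rats for immediate early genes (adjusted p = 1.7e-06, and 0.373 estimated), oxidative phosphorylation (median 0.05, adjusted p = 1.2e-05, and 0.547), cortical markers (median -0.25, adjusted p = 0.011, and 0.713; 0.052 without rat 28) and dyskinesia-linked genes (median -0.11, adjusted p = 0.022, and 0.547; ended by leaving out any 1 of 10 rats, up to 0.083). The three-way term was called for oxidative phosphorylation (median -0.06) and striatal dopamine signalling (median 0.17), each with adjusted p = 0.013 (0.621 with an estimated correlation; with the array block 0.0027 and 0.063). It was also called for choroid plexus (median 0.57), microglia (median 0.48) and interferon genes (median 0.41), each with adjusted p = 0.014 (0.621, 0.623 and 0.621 with an estimated correlation; with the array block 0.063, 0.017 and 0.063). The others were cortical markers (median -0.41, adjusted p = 0.018), dyskinesia-linked genes (median 0.15, adjusted p = 0.020) and astrocytes (median -0.12, adjusted p = 0.033), each with adjusted p = 0.621 with an estimated correlation. With the array block these had adjusted p = 0.063, 0.056 and 0.085, so 2 of the 8 lists, oxidative phosphorylation and microglia, passed with the block. Without rat 2 the adjusted p was 0.634 for interferon genes and 0.680 for microglia, without rat 7 0.073 for choroid plexus and without rat 3 0.063 for striatal dopamine signalling. Any 1 of 6 rats ended the cortical call (up to 0.094), any 1 of 5 that of dyskinesia-linked genes (up to 0.094) and any 1 of 19 that of astrocytes (up to 0.139).

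Other splits of the rats were drawn 100 at a time, the labels' own included. As many calls as under the labels came up in 1 of 100 for the lesion (944 calls, highest other 2), L-dopa (40, highest other 1) and pramipexole (7, highest other 1). The same share was found for pramipexole in lesioned L-dopa rats (3, highest other 1). This is the smallest share that 100 splits can give, and it was read over 14 comparisons. It argues against chance without excluding it, and says nothing about the array step. The 3 calls in lesioned L-dopa rats are all of globin probe sets. Their count fell to 0 without rat 2, without the filter and with several covariates. The share was also under 0.05 for the lesion without drugs (2 of 100; 199 calls, highest other 453), L-dopa in lesioned rats (4 of 100; 3 calls, highest other 768) and lesion by L-dopa (2 of 100; 2 calls, highest other 2), but the values speak less firmly against chance there. Other splits gave as many calls or more, and which rats those with 453 and 768 separate was not examined. The first principal component of the 56 arrays held 9.3% of the variance and followed the cortical marker score (absolute r = 0.950). Whether this lies behind those splits was not tested. The splits do not argue against chance for pramipexole in sham L-dopa rats (5 of 100, with 8 calls, highest other 21) and L-dopa in sham rats (13 of 100, with 1 call, highest other 2). The splits were drawn without regard to the array set, over which the rats of these comparisons are divided. For the comparisons with 0 calls, 100 of 100 splits gave as many: pramipexole in lesioned saline rats (highest other 2), pramipexole in sham saline rats (1), lesion by pramipexole (2), L-dopa by pramipexole (1) and the three-way term (2).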

How the results depend on the processing

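The array block, the cortical covariate, the fits without rat 2 and without each rat in turn, for counts and for lists, and the added 16 were chosen after seeing the data. Of the 69 calls of named genes, the array block kept 3, ended 60 and reversed 6. Of those 3, Peli2 and Hbb in lesioned L-dopa rats compare groups that lie in 1 set of arrays, where the block cannot move the change. No filter kept 46, the 3' to 5' covariate 50, quantile normalization 57, the cortical covariate 62, array weights 63, the choroid plexus covariate 64, the fit without rat 2 64, the trend with a robust prior 65 and the added 16 kept 67. Fewer samples in the fit kept 41 of 67 and the filter at the 60th percentile 40 of 40. Genes past the threshold in neither fit count as unmoved even where their sign changed, and only lists called in the report were followed. Of 59 list calls, 56 were lost with an estimated correlation; the other 3 are the blood list of 1 gene. The array block ended 16 of the 59, which include calls of groups lying in 1 set of arrays, where the block cannot move the change. The 3' to 5' covariate ended 29, not all of them named above, with 1 more reversed. The cortical covariate ended 17 and reversed 4, the choroid plexus covariate ended 13 and reversed 2, and the filter at the 60th percentile ended 12. No filter ended 8. Quantile normalization, array weights and the fit without rat 2 ended 5 each, the last with 1 more reversed. Leaving out single rats of the compared groups ended 37 of the 59, and 11 of these depended on 1 rat only.

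With the array block 0 probe sets were called for the lesion, L-dopa, pramipexole in sham L-dopa rats, the lesion without drugs, L-dopa in sham rats and lesion by L-dopa. The block changed the sign of Gosr1 (-0.27) and C8h11orf87 (-0.020) for the lesion, Myh1 for L-dopa (-0.0057), Jund for pramipexole in sham L-dopa rats (-0.046), and Gosr1 (-0.41) and Cox5a (-0.031) for the lesion without drugs. Without the filter 0 were called for pramipexole in lesioned L-dopa rats, for L-dopa in lesioned and in sham rats and for lesion by L-dopa, where more probe sets were tested. With the filter at the 60th percentile there were 6 calls for L-dopa in lesioned rats and 5 in sham rats. Quantile normalization, which moved the median of all probe sets by 0.021 for the lesion, gave 1 for L-dopa in lesioned rats, 4 in sham rats and 9 for lesion by L-dopa; it also gave 468 higher and 416 lower for the lesion, and 186 and 46 without drugs. The trend with a robust prior gave 1 for lesion by L-dopa. Array weights gave 6 for pramipexole in lesioned L-dopa rats, 2 in lesioned saline rats, 6 for L-dopa in sham rats and 6 for lesion by L-dopa. With the 3' to 5' covariate there were 18 for L-dopa, 0 for pramipexole in lesioned L-dopa rats, 1 in lesioned saline rats, 125 for the lesion without drugs, 1 for L-dopa in lesioned rats, 6 in sham rats and 8 for lesion by L-dopa, and the glutamate list in L-dopa in lesioned rats turned to -0.0031. With the choroid plexus covariate there were 0 for pramipexole in lesioned L-dopa rats, 1 in lesioned saline rats, 0 for L-dopa in lesioned rats and 5 in sham rats, and the choroid plexus list itself, which the covariate removes, went to -0.098 in pramipexole in lesioned L-dopa rats and to 0.013 in the three-way term. With fewer groups in the fit, or an additive model for main effects, there were 22 for L-dopa, 50 for the lesion without drugs and 0 for pramipexole in lesioned L-dopa and in sham L-dopa rats and for L-dopa in lesioned and in sham rats. With the cortical covariate there were 0 for pramipexole in lesioned L-dopa rats, 1 in sham saline rats, 0 for L-dopa in lesioned rats, 10 in sham rats, 7 for lesion by L-dopa and 1 for L-dopa by pramipexole. The cortical list, which that covariate removes, went to 0.0055 in pramipexole in lesioned saline rats, -0.00346 in L-dopa in lesioned rats and 0.051 in L-dopa by pramipexole, and striatal dopamine signalling in L-dopa in lesioned rats to 0.0018. Without rat 2 there were 0 for pramipexole in lesioned L-dopa rats and 1 in lesioned saline rats, and interferon genes in the former turned to -0.010. The added 16 gave 1 for pramipexole in lesioned saline rats and 1 for lesion by L-dopa. Except where a covariate removes its own list or more probe sets were tested, the cause was not tested.

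Leaving out each rat in turn gave 799 to 1095 calls for the lesion, 28 to 62 for L-dopa (62 without rat 15, in lesioned rats given saline and pramipexole) and 6 to 8 for pramipexole. Over the alternatives other than the block, the lesion gave 744 to 1209 calls and pramipexole 6 to 8. In the 20 cases above where limma called 0 in place of a higher count, 640 to 3103 probe sets had unadjusted p under 0.05. The planned pseudocounts of 1 and 64 were not run, as the deposited values were already on the log2 scale. No paired analysis was possible because rat numbers are not shared between groups. Dim signals limit the arrays: Th and Drd3 lay below the filter, and Cd93 and Fosb (mean 5.15) lay near it.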
